A study of Arabidopsis thaliana with 2 samples.

How the data were processed

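Expression was measured in 2 poly(A) RNA libraries of Arabidopsis thaliana early globular embryos, 1 wild type (Col-0) and 1 dcl1-5, with 30 embryos pooled in each (n = 1 per genotype). Groups were taken from the strain names in the sample labels. Per the labels' protocols, plants grew under 16 hours of light and 8 hours of dark, embryos were dissected by hand, and the RNA went through 2 rounds of linear amplification before strand-specific libraries were made.

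Per the series' design text, the authors aligned reads to the TAIR9 assembly with Bowtie, allowed up to 2 mismatches in a 25 nt seed, kept uniquely mapped reads, and counted the antisense strand because the amplified RNA is antisense. The Bowtie version is not given in the sources used here. The deposited values are RPM, in which reads were normalised to the genome-matching reads of each library, per the labels and the file headers. Discarding multiply mapped reads lowers the values of genes with near-identical copies. The deposited table also holds a ratio (fold) column by the authors, which equalled the quotient of the 2 RPM columns within 9.35e-07 and was not used.

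The RPM values of each library were whole multiples of 1 read, within 0.01 reads for 100% of values, so reads were recovered. This gave 5611643 genome-matching reads in wild type and 4513588 in dcl1-5, of which 90.2% and 88.0% lay in listed genes. The floor of 3 reads was 0.535 RPM and 0.665 RPM. The table listed 20612 loci, and none was at 0 in both libraries. Of these, 20509 were paired by identifier with the RefSeq annotation of TAIR10.1. That assembly differs from the authors' TAIR9 build, so it was used for names, products and overlapping loci, and no coordinates are printed. Among neighbouring rows with 20 or more reads in total, identical reads in both libraries were found in 51 cases, and whether these are overlapping loci was not tested. Of the 125 genes named by rule, 38 overlap another locus in that annotation, OLEO1, OLEO2, L1L, EEL, GL2, FIS2, ADH1 and CSD1 among them, and their values are uncertain where the partner lies on the same strand.

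The log2 ratio was log2((dcl1-5 RPM + 1) / (wild-type RPM + 1)), which understates changes of low genes. Genes with a mean of at least 5 RPM over both libraries were tested, and a ratio of at least 2-fold was counted. Printed folds are plain RPM ratios, which can pass a threshold that the log2(RPM + 1) scale does not. RPM values have exact Poisson 95% intervals and ratios have exact conditional (Clopper-Pearson) 95% intervals. A gene with 0 reads in 1 library is compared with the floor of 3 reads, and the exact lower bound of its fold, which is smaller, is given beside it. Each gene list's median was placed among 10000 random lists of the same size drawn within 20 bins of mean expression, and it stood apart at a percentile of at most 2.5 or at least 97.5. A list needed 3 genes at 5 RPM. This describes the 2 libraries and is no test of the genotypes. All 29 single lists and these rules were fixed before the data were examined, as were the named genes: DCL1, the 15 highest and 15 lowest log2 ratios, up to 4 members per list with the largest absolute log2 ratio, and every miRNA target at least 4-fold different, all at a mean of at least 5 RPM apart from DCL1. A few other list members are named with their values and were chosen after these were seen. They are REV, CMT3, CUC1, TOE1, TOE3, TAS3B, TASIR-ARF, MIR775, MIR402, MIR408, LEC1, the SPL, storage and LEA genes under the filter, PLT1, SCR, WOX8 and WOX9. The members of the MIRNA list were the 36 loci of the table annotated as MIRNA genes, by a rule fixed beforehand. Those of the other lists were written from general knowledge and checked against the annotation, where 27 of 384 had another symbol or only a locus name for the same gene. The union of the miRNA target lists was tested as well.

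Alternatives were pseudocounts of 0.1 and 5 RPM, no filter, a mean of at least 20 RPM, equal totals, median-of-ratios scaling, TMM scaling (edgeR 4.0.16 on the recovered reads, in R 4.3.3), a 4-fold threshold, unmatched random lists, the mean in place of the median, and an exact conditional binomial test per gene with Benjamini-Hochberg adjustment at 0.05. The median-of-ratios factor was taken from genes at a mean of at least 20 RPM. A lowess correction for expression (fraction 0.3), thinning of the wild-type reads, and counts of list and family members after subtracting the median of all genes were added after seeing the data. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6. The calculations were tested on data simulated for dcl1-5 against wild type with counting noise only, over 10224 genes. All simulated 4-fold and 8-fold changes in either direction passed the 2-fold rule (100%), as did 26.5% of 2-fold increases, 51.5% of 2-fold decreases and 0.0299% of unchanged genes. Of 1000 unchanged lists of 15 genes 4.90% were called, and 100% of lists of that size shifted by 1 log2 unit. This does not give the power for smaller lists or for genes that vary beyond counting noise. The simulation also held no shift between the libraries, whereas the median log2 ratio of the data was 0.63. Its rates are therefore not those of the 2-fold rule in the data. For the 3 endosperm markers tested, matched lists ran from -0.59 to 2.09 between percentiles 2.5 and 97.5, around a median of 0.80. A shift of 1 log2 unit can therefore stay within matched lists when a list is small.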

Results

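Poly(A) RNA was profiled by strand-specific mRNA-Seq in early globular embryos of Arabidopsis thaliana, a stage at which the embryo is a small ball of cells. There were 2 libraries, 1 from wild-type Col-0 embryos and 1 from dcl1-5 embryos, each made from a pool of 30 hand-dissected embryos. The dcl1-5 line carries a mutation in DICER-LIKE1 (DCL1), the enzyme that cuts plant microRNAs (miRNAs) out of their precursors. The values are RPM, in which the reads of each gene are scaled to all genome-matching reads of its library, from 5611643 such reads in wild type and 4513588 in dcl1-5, so that 1 read stood for 0.178 RPM and 0.222 RPM. With 1 library per genotype no difference below has a replicate check, and no p-value is given for the genotypes. Intervals in brackets are exact 95% intervals. They cover counting error only, since the RNA was amplified and its reads are not independent molecules. Values of genes that overlap another locus, of which there are 38 among the 125 genes named by rule, are less certain, and so are those of near-identical gene copies. The digit after AT in a gene identifier is its chromosome.

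DCL1 (AT1G01040) itself was lower in the dcl1-5 library. It had 26 reads, or 4.63 RPM [3.03 to 6.79], in wild type and 3 reads, or 0.665 RPM [0.137 to 1.94], in dcl1-5, a ratio of 6.97 [2.14 to 36.0]. These are totals over the whole gene, so they do not show which part of the transcript was read, and other loci overlap DCL1 in the reference annotation.

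The first comparison asked how many transcripts differed between embryos with and without normal DCL1. Of 10240 genes with a mean of at least 5 RPM, 3464 were at least 2-fold higher and 469 at least 2-fold lower in dcl1-5 on the log2(RPM + 1) scale, so that 88.1% of the differing genes were higher. This split depended on the scaling. It was 1984 higher and 1091 lower (64.5% higher) after median-of-ratios scaling, and 1535 higher and 1487 lower (50.8% higher) after TMM scaling. The median log2 ratio of all tested genes was 0.63 with the authors' scaling, 0.18 with median-of-ratios and 0.00 with TMM. A gene list was therefore compared with random lists of the same size and similar expression, which carry a similar shift. The distance of its median from 0.63 is given for some lists. Counts called net of the shift were made after 0.63 was subtracted from each gene's log2 ratio, and they are given for each tested list where they differ from the first count. The shift fell with expression, from a median of 0.86 in the lowest 10% of genes by mean RPM to 0.06 in the highest 10%. Net counts and distances from 0.63 therefore lean towards lower for abundant genes and towards higher for low ones. All 3464 higher and all 469 lower genes also passed an exact binomial test on their reads, which compares these 2 libraries and not the genotypes. As 7510 of the 10240 genes passed it, passing adds little to the 2-fold rule. The 100 most abundant loci took 35.8% of the genome-matching reads in wild type and 24.4% in dcl1-5.

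The transcripts that plant miRNAs are known to target were higher in dcl1-5 as a group. Of 55 measured targets, 39 were at least 2-fold higher, 3 were at least 2-fold lower and 13 differed by less, and net of the shift 23 were higher and 4 lower. Their median log2 ratio was 1.498, which is 0.87 above that of all genes and above all 10000 matched random lists. On the log2(RPM + 1) scale, at least 4-fold differences were seen for 17 targets, of which 16 were higher and 1 was lower.

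**Figure D1:**
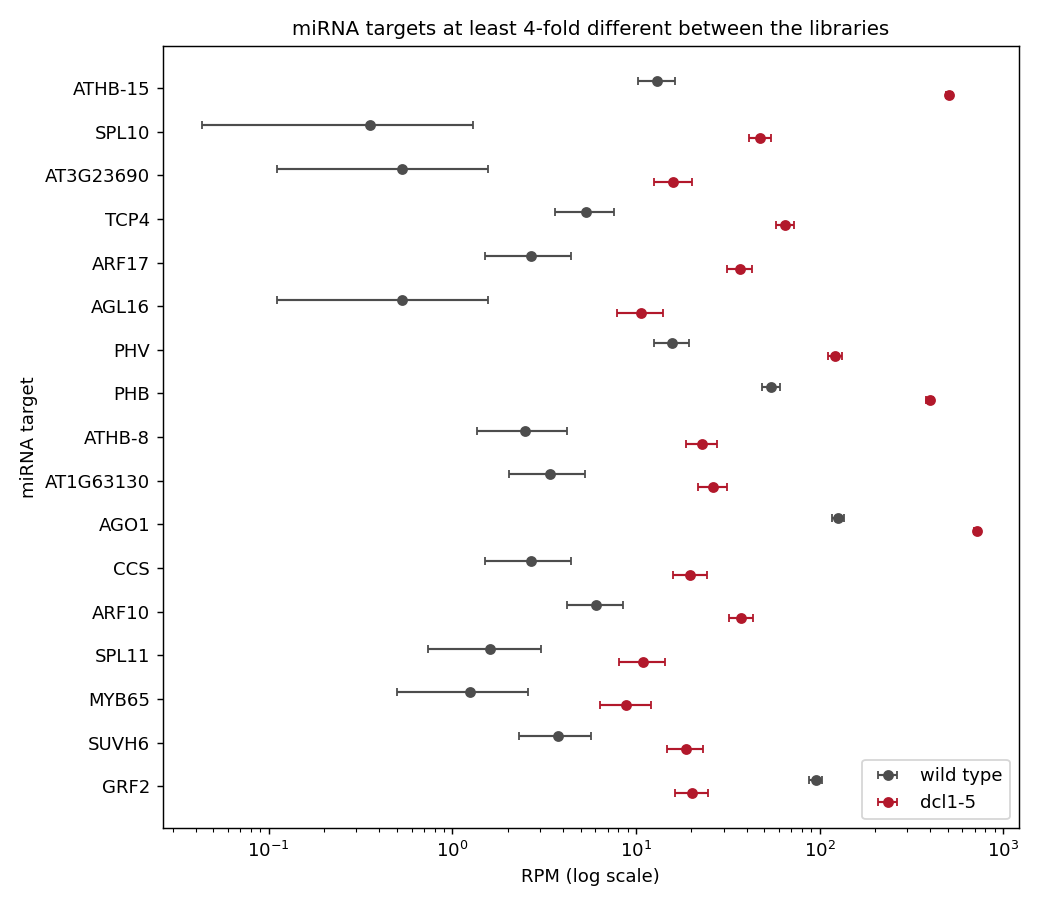
RPM on a log scale in the wild-type library (grey) and the dcl1-5 library (red) for the 17 miRNA targets at least 4-fold different between them on the log2(RPM + 1) scale, with bars for exact 95% Poisson intervals of the reads. The point for each of 16 targets lies higher in dcl1-5, with ATHB-15 moving from 13.0 to 506.0 RPM, and GRF2 moves the other way, from 94.98 to 20.2 RPM.

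The targets of miR165 and miR166, class III homeodomain-leucine zipper factors that set adaxial and vascular identity, were all at least 2-fold higher, 4 of 5 net of the shift. ATHB-15 (AT1G52150) went from 13.0 to 506.0 RPM, a 38.9-fold difference [30.8 to 49.8]. PHB (AT2G34710) went from 54.4 to 397.7 RPM, 7.32-fold [6.48 to 8.29], and PHV (AT1G30490) from 15.7 to 121.4 RPM, 7.74-fold [6.17 to 9.81]. ATHB-8 (AT4G32880) was 9.15-fold higher [5.21 to 17.3], and REV (AT5G60690) went from 7.84 to 18.8 RPM. The median log2 ratio of these 5 genes was 2.85, 2.22 above all genes, and no random list lay above it.

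Among the SPL transcription factors targeted by miR156, 3 of the 8 listed in the table reached a mean of 5 RPM. Under the filter, SPL6 had 0 reads in wild type and 35 in dcl1-5, and SPL9 had 0 and 25. SPL15 had 3 and 24 reads and SPL2 had 10 and 31. SPL4 had 1 and 5, with an interval that includes equality. SPL10 (AT1G27370) had 2 reads in wild type and 214 in dcl1-5, from 0.356 to 47.4 RPM, a ratio of 133 [36.4 to 1106]. SPL11 (AT1G27360) went from 1.60 to 10.9 RPM, 6.77-fold [3.29 to 15.7]. SPL3 (AT2G33810) had 4.28 and 6.87 RPM, a ratio of 1.61 whose interval of 0.912 to 2.86 includes equality, and another locus overlaps it. The list's median log2 ratio of 2.19 lay at percentile 98.2 of matched lists, and at 97.3, within them, with a pseudocount of 5 RPM. For miR159 and miR319, 3 of 4 measured targets were at least 2-fold higher, with a median of 2.04 at percentile 99.6. TCP4 (AT3G15030), a factor that promotes differentiation, went from 5.35 to 64.9 RPM, 12.1-fold [8.33 to 18.3]. TCP3 (AT1G53230) went from 19.4 to 77.8 RPM, and MYB65 (AT3G11440) from 1.25 to 8.86 RPM. TCP2 (AT4G18390) was 1.77-fold higher [1.31 to 2.42], short of the 2-fold rule.

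The auxin response factors (ARFs) and the amidohydrolase targeted by miR160 and miR167 had a median of 1.42, at percentile 96.5 and so within matched lists, and 4 of 5 were at least 2-fold higher, or 2 net of the shift. This call depended on the statistic: the list stood above matched lists at percentile 98.7 when its mean was used. ARF17 (AT1G77850) was 13.8-fold higher [8.10 to 25.1] and ARF10 (AT2G28350) 6.18-fold [4.26 to 9.22]. ARF8 (AT5G37020) and ARF6 (AT1G30330) were 2.71-fold and 2.22-fold higher. Other targets at a median of 1.56 and percentile 99.8 had 9 of 12 members at least 2-fold higher and 1 lower, or 4 and 1 net of the shift. They included AGO1 (AT1G48410), the main miRNA effector and itself a target of miR168, which went from 126.2 to 720.7 RPM, 5.71-fold [5.26 to 6.20]. AGL16 (AT3G57230), the miR824 target, went from 0.535 to 10.6 RPM, 19.9-fold [6.41 to 99.8], on 3 wild-type reads. AT1G63130, a pentatricopeptide repeat protein, was 7.72-fold higher and SUVH6 (AT2G22740), a histone methyltransferase, 4.97-fold. The DNA methyltransferase CMT3 was the member at least 2-fold lower, with 144.5 RPM in wild type and 64.0 in dcl1-5. It was named after its value was seen. At a mean of at least 20 RPM the median of this list was 1.23, at percentile 96.2 and so within matched lists. Targets in metal, sulfate and phosphate use had 8 of 9 members at least 2-fold higher, or 4 net of the shift, with a median of 1.498 at percentile 99.3. The superoxide dismutase chaperone CCS (AT1G12520) was 7.38-fold higher [4.24 to 13.7] and CSD1 (AT1G08830) went from 164.5 to 560.8 RPM. UBC24 (AT2G33770) was 4.68-fold higher and APS1 (AT3G22890) 3.44-fold.

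Not every target family followed. The growth-regulating factors targeted by miR396 had 2 members at least 2-fold lower, 1 higher, or 0 net of the shift, and 1 neither, and their median of -0.78 lay at percentile 0.30, below matched lists. GRF2 (AT4G37740) was 4.71-fold lower [3.77 to 5.95] and GRF3 (AT2G36400) 2.69-fold lower [1.95 to 3.76], whereas GRF1 (AT2G22840) was 2.26-fold higher [1.68 to 3.06]. GRF9 (AT2G45480) had 9.62 and 8.20 RPM. With no expression filter the list's percentile was 3.92, within matched lists, at the median of a member with 1 read in wild type and 0 in dcl1-5. For miR169 targets the median was 0.05, at percentile 13.0, and it turned negative with median-of-ratios and TMM scaling (-0.42 and -0.61). NF-YA1 (AT5G12840) was 4.45-fold higher [2.85 to 7.16]. NF-YA3 (AT1G72830) had 101.6 and 85.1 RPM, NF-YA5 (AT1G54160) had 83.6 and 76.0 RPM, and NF-YA9 (AT3G20910) had a log2 ratio of 0.24 that turned to -0.23 and -0.42 with those scalings. The miR393 and miR394 targets had a median of 0.31 at percentile 21.9, which likewise turned negative (-0.15 and -0.34). Of its 5 members 2 were at least 2-fold higher and 0 lower, and net of the shift 2 were higher and 1 lower. Within that list AT3G23690, a basic helix-loop-helix factor, was 29.8-fold higher [9.81 to 148] on 3 wild-type reads, and LCR (AT1G27340) was 4.08-fold higher. The auxin receptor AFB2 (AT3G26810) was 1.86-fold lower [1.44 to 2.42]. The auxin receptor TIR1 (AT3G62980) had 29.6 and 37.0 RPM, a difference that changed direction with the same scalings.

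The target lists of miR164, of miR170 with miR171, and of miR172 had fewer than 3 genes at 5 RPM and were not tested. HAM2 (AT3G60630) was 4.05-fold and SCL27 (AT2G45160) 2.86-fold higher among the miR170 and miR171 targets. TOE2 (AT5G60120) was 3.94-fold [2.01 to 8.28] and AP2 (AT4G36920) 2.16-fold higher among those of miR172, whereas under the filter TOE1 had 23 reads in wild type and 4 in dcl1-5, 4.62-fold lower [1.58 to 18.4], and TOE3 had 3 and 24. All 6 miR164 targets were below the filter, and CUC1 had 23 reads in wild type and 11 in dcl1-5. Of genes that SPL factors regulate in flowering, which were also not tested as a list, FT (AT1G65480) went from 4.28 to 30.1 RPM, 7.05-fold [4.54 to 11.4].

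Few primary transcripts of MIRNA genes reached a mean of 5 RPM, and the 4 that did were higher in dcl1-5. The table listed 36 MIRNA loci, of which 25 had more RPM in dcl1-5 and 11 more in wild type, but 32 were under a mean of 5 RPM. The other 4 were all at least 2-fold higher, with a median log2 ratio of 2.997 that lay above all 10000 matched lists. These 4 had between 1.25 and 3.21 RPM in wild type, so they reached the mean of 5 RPM through their dcl1-5 values. MIR156c (AT4G31877) went from 3.21 to 113.7 RPM, 35.4-fold [22.2 to 60.3], and MIR167a (AT3G22886) from 1.25 to 33.2 RPM, 26.6-fold [12.6 to 67.4]. MIR169a (AT3G13405) was 5.97-fold and MIR162a (AT5G08185) 5.43-fold higher. Under the filter, MIR775 had 35 reads in wild type and 0 in dcl1-5 and MIR402 had 13 and 0, while MIR408 had 1 and 41. Over all 36 loci with no filter the median was 0.29, at percentile 95.1 and so within matched lists. That median equals the value of a locus with 1 read in wild type and 2 in dcl1-5, under the floor of 3 reads.

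Trans-acting siRNA loci and their ARF targets lay within matched lists, with a median of 0.59 at percentile 65.8 that was -0.06 with TMM scaling. Of 4 members 1 was at least 2-fold higher and 1 lower, or 0 and 1 net of the shift. TAS3 (AT3G17185), whose RNA yields the siRNAs against ARFs, was 2.06-fold higher [1.86 to 2.30], and its target ETT (AT2G33860) was 2.71-fold lower [2.39 to 3.09]. Under the filter, TAS3B had 13 reads in wild type and 0 in dcl1-5, with an exact lower bound of 2.45-fold lower, and TASIR-ARF had 5 and 0. ARF2 (AT5G62000) was 1.88-fold higher. ARF4 (AT5G60450) had a log2 ratio of 0.27 that changed sign under median-of-ratios and TMM scaling. Genes of the RNA silencing machinery had 9 of 16 members at least 2-fold higher and none at least 2-fold lower, or 2 higher and 0 lower net of the shift, with a median of 1.06 at percentile 95.7, within matched lists. AGO7 (AT1G69440) was 4.57-fold, DCL4 (AT5G20320) 5.08-fold, SGS3 (AT5G23570) 3.81-fold and RDR1 (AT1G14790) 2.85-fold higher.

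Oleosin genes were among the most different. All 4 measured members of the seed storage, oil body and LEA list were oleosins, the coat proteins of oil bodies. Their median log2 ratio of 6.42 lay above all matched lists. These 4 had 1 or 2 reads in wild type, so they reached the mean of 5 RPM through their dcl1-5 values. The 6.42 therefore describes these 4 genes and not the whole list. OLEO3 (AT5G51210) had 2 reads in wild type and 972 in dcl1-5, or 0.356 and 215.3 RPM, a ratio of 604 [167 to 4996]. OLEO1 (AT4G25140), OLEO4 (AT3G27660) and OLEO2 (AT5G40420) each had 1 wild-type read and reached 106.6, 93.7 and 66.0 RPM in dcl1-5. Seed coat markers were higher in the same library too, with a median of 1.21. The other 9 members in the table were under the filter. Of the storage proteins SESA3 had 0 reads in wild type and 36 in dcl1-5, CRA1 had 0 and 12, SESA4 had 0 and 9, and SESA2 had 0 and 1. The remaining members, such as LEA proteins, showed no difference that could be detected at this depth, with 1 and 0 reads for PER1, EM6 and ECP63 each, 1 and 3 for RAB28, and 3 and 6 for RAB18. Regulators of seed maturation had 5 of 9 members at least 2-fold higher, or 3 net of the shift, a median of 1.52 and percentile 99.5. EEL (AT2G41070) was 16.0-fold higher [8.70 to 32.9] and L1L (AT5G47670) went from 18.4 to 181.5 RPM, 9.89-fold [8.05 to 12.3]. BZIP10 (AT4G02640) was 4.74-fold and BZIP25 (AT3G54620) 3.299-fold higher. LEC1, a master regulator of the programme, had 250.7 and 286.9 RPM. At a mean of at least 20 RPM this list's median was 0.72, at percentile 78.4 and so within matched lists. Fatty acid and oil synthesis genes lay within matched lists (median 0.74, percentile 90.12), with 4 of 12 at least 2-fold higher, or 3 net of the shift. BCCP2 (AT5G15530) was 5.39-fold, GPAT9 (AT5G60620) 3.41-fold, ACP1 (AT3G05020) 3.14-fold and FAB2 (AT2G43710) 2.16-fold higher.

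All 20 photosynthesis genes had positive log2 ratios and 19 were at least 2-fold higher, or 17 net of the shift. Their median of 1.85 was 1.22 above that of all genes and above all 10000 matched lists. PSAD-1 (AT4G02770), a photosystem I subunit, went from 6.77 to 96.2 RPM, 14.2-fold [10.2 to 20.3]. The light-harvesting proteins LHCB1.3 (AT1G29930), LHCA3 (AT1G61520) and LHCB5 (AT4G10340) were 6.35-fold, 5.93-fold and 5.16-fold higher. LHCB1.3 has near-identical copies, so its uniquely mapped reads are a partial count. Markers of the seed coat, a maternal tissue around the embryo, were also higher in the dcl1-5 library, with 5 of 10 at least 2-fold higher, or 3 net of the shift, a median of 1.21 and percentile 98.0. BAN (AT1G61720) went from 32.6 to 124.5 RPM, 3.82-fold [3.23 to 4.54]. GL2 (AT1G79840), TT1 (AT1G34790) and DFR (AT5G42800) were 4.68-fold, 5.25-fold and 2.99-fold higher. This list was within matched lists with a pseudocount of 5 RPM (percentile 95.3) and against unmatched lists (95.5). Only 3 endosperm markers reached 5 RPM, and their median of 0.95 lay at percentile 59.1. They were FIS2 (AT2G35670), 22.0-fold higher [7.12 to 110] on 3 wild-type reads, FWA (AT4G25530), with 13.5 and 27.0 RPM, and SUC5 (AT1G71890), 1.68-fold higher.

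Genes that pattern the basal embryo, root and suspensor stood below matched lists. Of 18 measured, 7 were at least 2-fold lower, 4 at least 2-fold higher, or 3 net of the shift, and 7 neither, and the median of -0.16 was 0.79 below that of all genes, at percentile 0.01. TMO6 (AT5G60200), a target of the auxin response factor MONOPTEROS, had 167 reads in wild type (29.8 RPM) and 0 in dcl1-5, at least 44.8-fold lower against a floor of 3 reads, with an exact lower bound of 36.0-fold. TMO3 (AT4G23750) was 18.6-fold lower [9.61 to 41.2] and WOX5 (AT3G11260), a marker of the root organiser, 5.81-fold lower [2.88 to 13.3]. The root regulators PLT1 and SCR went from 104.4 to 43.4 RPM and from 29.4 to 9.31 RPM. GN (AT1G13980), WOX8 and WOX9 were higher, GN by 5.21-fold [3.37 to 8.33]. WOX8 went from 4.28 to 16.2 RPM and WOX9 from 8.91 to 29.9 RPM. At a mean of at least 20 RPM the percentile was 3.53, within matched lists. Apical and shoot patterning genes lay within matched lists (median 0.35, percentile 18.1), with a median of -0.11 and -0.30 under median-of-ratios and TMM scaling. Of 6 members 2 were at least 2-fold higher and 1 lower, or 2 and 2 net of the shift. DRN (AT1G12980) was 13.4-fold lower [6.88 to 29.9], while AS2 (AT1G65620) was 7.46-fold and AS1 (AT2G37630) 3.55-fold higher. TPL (AT1G15750) was 1.48-fold higher, with its sign reversed under TMM scaling. With no filter the percentile of the list was 1.08, below matched lists. Its median there, -0.24, equals the value of a gene with 1 read in wild type and 0 in dcl1-5. That is under the floor of 3 reads, so this call says little about the list.

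Epidermal genes lay within matched lists (median 0.72, percentile 87.6), and 5 of 11 were at least 2-fold higher and 0 lower, or 2 and 1 net of the shift. GSO2 (AT5G44700) was 6.25-fold, HDG2 (AT1G05230) 3.73-fold, ACR4 (AT3G59420) 3.47-fold and CER6 (AT1G68530) 2.52-fold higher. Auxin genes did so too (median 0.80, percentile 65.3), with 5 of 12 at least 2-fold higher and 2 lower, or 3 and 2 net of the shift. The conjugating enzyme GH3.5 (AT4G27260) was 40.4-fold higher [10.7 to 341] on 2 wild-type reads. The biosynthetic enzyme TAA1 (AT1G70560) was 7.73-fold higher [4.95 to 12.6], IAA19 (AT3G15540) 3.86-fold higher, and YUC4 (AT5G11320) 5.07-fold lower [2.58 to 11.1]. Cell division genes had a median of 0.05 at percentile 2.52, just inside the limit of 2.5, and stood below matched lists under 5 alternative settings. Their median was -0.41 and -0.60 under median-of-ratios and TMM scaling. Of 19 members 2 were at least 2-fold higher and 1 lower, or 0 and 4 net of the shift. PCNA1 (AT1G07370), the replication clamp, was 2.32-fold lower [2.01 to 2.69] and MCM5 (AT2G07690), with 13.4 and 6.20 RPM, was just short of the 2-fold rule, whereas CYCB1;1 (AT4G37490) and CYCD3;1 (AT4G34160) were 2.22-fold and 2.44-fold higher.

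Stress and reference genes gave the background. Heat and handling stress genes lay within matched lists (median 0.92, percentile 94.8), with 7 of 17 at least 2-fold higher and 1 lower, a balance that turned to 2 higher and 3 lower net of the shift. ADH1 (AT1G77120) went from 27.6 to 222.2 RPM, 8.05-fold [6.79 to 9.59]. WRKY40 (AT1G80840) was 7.26-fold and WRKY33 (AT2G38470) 3.37-fold higher, and the small heat shock protein HSP17.4 (AT3G46230) was 3.79-fold lower [2.51 to 5.92]. Housekeeping reference genes had a median of 0.26 at percentile 42.5, which was -0.18 and -0.37 under median-of-ratios and TMM scaling. Of 14 members 2 were at least 2-fold higher and 0 lower, or 0 and 1 net of the shift. UBC9 (AT4G27960) and AT4G34270 were 2.35-fold and 2.21-fold higher, CYP5 (AT2G29960) had 16.9 and 33.9 RPM, and TUA4 (AT1G04820) was 1.61-fold lower.

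**Figure D2:**
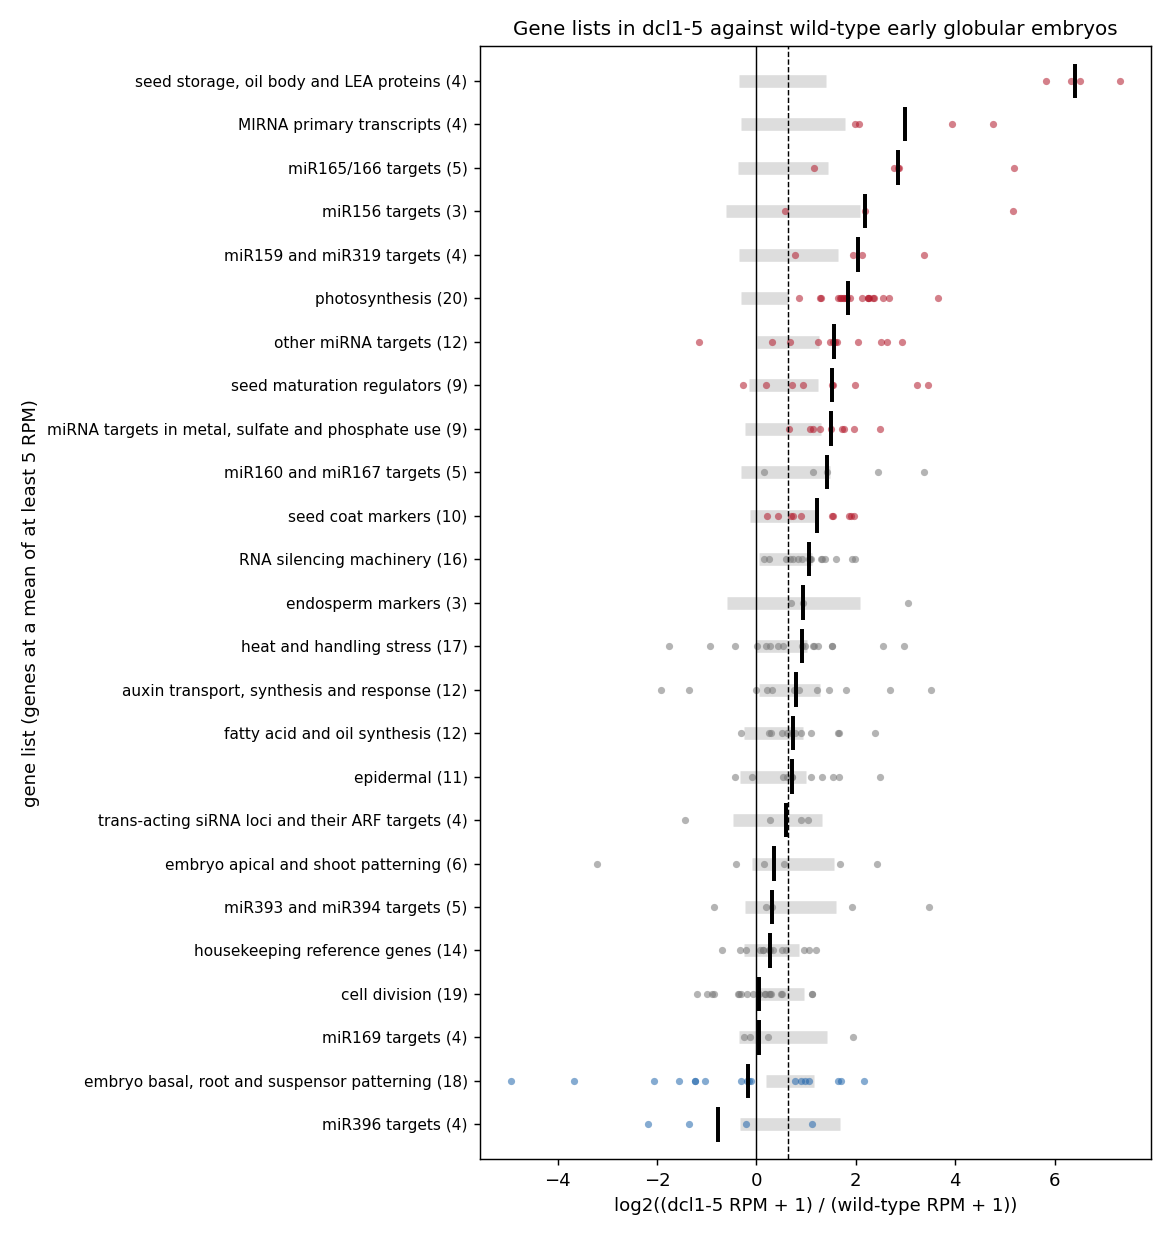
Log2 ratio of dcl1-5 to wild type, from RPM + 1, for each gene at a mean of at least 5 RPM in the 25 single lists tested (points, with the number of genes in brackets), with a black tick at each median, a grey bar for the middle 95% of 10000 matched random lists, and points in red for lists above, blue for lists below and grey for lists within that range. Oleosins have the highest median, 6.42, and miR396 targets the lowest, -0.78, against a solid line at 0 and a dashed line at the median of all genes, 0.63. The oleosins and the MIRNA transcripts reached the mean of 5 RPM through their dcl1-5 values. The medians of the miR169, miR393 and miR394, apical, cell division and housekeeping lists turn negative under median-of-ratios and TMM scaling. That of the trans-acting siRNA list does so under TMM scaling.

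Among the 15 genes with the highest log2 ratios were ATHB-15, SPL10, MIR156c and the 4 oleosins already described. AT3G01570, another oleosin family gene, went from 0.178 to 114.8 RPM. The highest ratio was that of AT1G04660, a glycine-rich protein gene, with 17 reads in wild type and 22328 in dcl1-5, or 3.03 and 4947 RPM. AT4G15390, an acyltransferase family gene, and AT1G65090 had 0 wild-type reads and were at least 123-fold and at least 80.0-fold higher against the floor of 3 reads, with exact lower bounds of 99.8-fold and 64.4-fold. AT3G13175, CLE27 (AT3G25905), AT5G38160 and AT5G25490 reached 116.5, 49.4, 156.2 and 257.0 RPM from 1.25, 0.178, 3.56 and 7.84 RPM. CLE27 encodes a small peptide of the CLAVATA3 family.

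The 15 lowest included TMO6 and TMO3. AT3G15680, a zinc finger gene, went from 343.6 to 1.55 RPM, 222-fold lower [107 to 552]. AT1G21090, annotated as a cupredoxin, went from 616.4 to 44.3 RPM, 13.9-fold lower [12.1 to 16.1]. ACI1 (AT5G01370) and NAS4 (AT1G56430) had 0 reads in dcl1-5 and were at least 31.6-fold and at least 24.4-fold lower against the same floor, with exact lower bounds of 25.3-fold and 19.4-fold. The aquaporin PIP2;8 (AT2G16850) had 192 reads in wild type and 1 in dcl1-5, and SAP (AT5G35770) had 216 and 2. The root patterning factor JKD (AT5G03150) was 36.7-fold lower [12.3 to 180], ERF5 (AT5G47230) 42.2-fold, SLY2 (AT5G48170) 33.2-fold and AT5G59000 35.8-fold lower. BCP1 (AT1G24520), RALFL4 (AT1G28270) and VGD1 (AT2G47040), which are known from pollen, were 35.0-fold, 32.8-fold and 47.9-fold lower.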

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

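No paired analysis was possible because each genotype has 1 library, and for the same reason no replicate could be left out. The lowess correction, the thinning and the counts net of the shift were chosen after seeing the data. Genes at least 2-fold higher and lower numbered 3464 and 469 as reported, 5706 and 1154 with no filter, 1243 and 220 at a mean of at least 20 RPM, and 801 and 83 at a 4-fold threshold, where the number of genes tested or the threshold itself sets the count. They numbered 1984 and 1091 with median-of-ratios scaling, 1535 and 1487 with TMM scaling, and 1360 and 1344 after the lowess correction, each of which moves the centre of the ratios. The exact binomial test called 6062 and 1448, as it has no minimum fold. The other settings, thinning included, stayed within 1.5 times. Of 229 recomputed list values 213 kept their call, 8 lost it, 8 gained it and 0 reversed. Calls were lost, by median log2 ratio, for miR156 targets (1.26) and seed coat markers (0.86) at a pseudocount of 5 RPM, for other miRNA targets (1.23), seed maturation regulators (0.72) and basal patterning genes (-0.16) at a mean of at least 20 RPM, for miR396 targets (-0.24) and MIRNA transcripts (0.29) with no filter, and for seed coat markers against unmatched lists (1.21). Calls were gained for miR160 and miR167 targets at a pseudocount of 5 RPM (1.35) and by the mean (1.70), and for apical patterning genes with no filter (-0.24), where the sign of the median also turned. Cell division genes gained a lower call at a mean of at least 20 RPM (-0.077), with median-of-ratios (-0.41) and TMM scaling (-0.60), against unmatched lists (0.055) and by the mean (-0.039). The miR396, MIRNA and apical medians with no filter equal values of genes under the floor of 3 reads. The cause of the list changes was not tested. Lists with fewer than 3 genes under a setting gave no value there. The log2 ratio of DCL1 was -1.76 as reported and -0.77 at a pseudocount of 5 RPM, which outweighs its few reads. Of 625 values recomputed for 125 named genes, 618 kept their sign, and the exceptions were genes under 2-fold. A kept sign is not a kept size, as 360 of these values were classed as the same and 265 as moved. Median-of-ratios and TMM scaling multiply each RPM ratio of dcl1-5 to wild type by 0.717 and 0.628. The intervals in brackets do not cover this choice of scaling. Depth limits genes near the floor of 3 reads, which is 0.535 RPM in wild type and 0.665 RPM in dcl1-5.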

Other observations

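The families in this paragraph, taken from annotated product names, were chosen after the data were seen, and of the tests in the paragraphs that follow, the scaling of the overall split and the seed coat test of the oleosins were chosen after their results were seen. There were 14, of which 4 stood above matched random lists, 4 below and 6 within, and 3 had their name patterns tightened after a first result because they took in unrelated proteins. Genes annotated as ribosomal proteins were lower in dcl1-5: 44 of 280 were at least 2-fold lower and 19 at least 2-fold higher (162 and 2 net of the shift), and their median log2 ratio of -0.50, which stayed negative under median-of-ratios (-0.98) and TMM scaling (-1.17), lay below all 10000 matched lists. The set mixes cytosolic proteins with some of organelles. Its share of the genome-matching reads was 26.3% in wild type and 15.2% in dcl1-5. Histones (median -0.45, 4 of 38 at least 2-fold lower and 21 net of the shift, percentile 0.06) also kept their sign under both scalings. Heat shock proteins (0.09, percentile 0.07) and elongation and initiation factors of translation (0.13, percentile 0.40) stood below matched lists, and both medians turned negative under both scalings. Their counts ran the other way until the shift was subtracted, with 12 of 55 heat shock proteins at least 2-fold higher and 5 lower, or 3 and 14 net of the shift, and 13 of 79 translation factors higher and 3 lower, or 2 and 21 net of the shift. The 0.63 subtracted exceeds the median of the highest 10% of genes by mean RPM, 0.06, so net counts of abundant families lean towards lower. Matched random lists, drawn within 20 bins of expression, lessen this lean. They may not remove it, since the highest 10% of genes ran from 131.6 to 33406.6 RPM. Photosystem and light-harvesting proteins were higher (median 2.02, 46 of 49 at least 2-fold higher and 40 net of the shift, above all 10000 lists). This family shares genes with the photosynthesis list fixed beforehand, LHCB1.3 among them, so it is not a separate observation. MYB transcription factors were higher too (1.25, 23 of 37 higher and 0 lower, or 14 and 1 net of the shift, percentile 99.9). Both medians were positive under both scalings. Protein kinases had a median of 0.86 at percentile 98.3 after tightening and 0.81 at percentile 99.2 before it, and of the 223 kept 95 were at least 2-fold higher and 8 lower, or 36 and 26 net of the shift. Seed storage and oleosin proteins depended on the tightening: 29 genes with the lipid transfer superfamily had a median of 0.74 at percentile 90.07, within matched lists, and 9 genes without it had 5.83, above all 10000 lists, which include the oleosins of the list fixed beforehand. Those within matched lists were F-box proteins (0.59), pentatricopeptide repeat proteins (0.53 after tightening, 0.48 before), lipid transfer proteins (0.69), late embryogenesis abundant (LEA) proteins (0.74), ubiquitin-conjugating enzymes (0.82) and cytochrome P450s (0.65). The F-box and pentatricopeptide repeat medians turned negative under TMM scaling. The LEA family takes in genes named as LEA hydroxyproline-rich glycoproteins. It does not stand for the LEA genes of the list fixed beforehand, which were under the filter.

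The excess of higher genes in dcl1-5 was weighed against depth and scaling. After the wild-type reads were thinned to the dcl1-5 depth, 88.2% of the differing genes were higher, so read number alone left the split as it was. RPM already divides by depth, so thinning could hardly have moved this share. It does not test other differences between the 2 libraries. Scaling cannot be told apart from a broad change of the transcriptome: the share was 64.5% after median-of-ratios scaling, between the bounds set for either reading, and 50.8% after TMM scaling, on the side that scaling as the cause would give, but both scalings re-centre the ratios, which itself pulls this share towards balance. The median-of-ratios factor was set by genes at a mean of at least 20 RPM, whose median was 0.47. It left a median of 0.18 over all tested genes, so the 64.5% depends on that choice. No spiked-in standard is named in the sources used here, and the genotype stays open as an untested explanation.

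Oleosin, photosynthesis and seed coat genes were all higher in dcl1-5, and seed coat tissue carried over in dissection is a candidate source. For the oleosins, the smallest lower bound of their folds, 65.99, exceeds the highest upper bound among 10 seed coat markers, 12.3. That would count against carry-over only if 1 source kept its genes in 1 ratio. The markers themselves ranged from 1.16-fold to 5.25-fold, so this comparison cannot decide, and carry-over stays open for the oleosins. For the photosynthesis genes the median fold of 3.74 lay inside that range of the seed coat markers. That comparison needs the same assumption of 1 ratio per source, so it cannot decide either. Carry-over cannot be told apart from a change in the embryo for these genes. Scaling alone does not account for the photosynthesis genes, whose median was 1.39 after median-of-ratios scaling. No biological explanation was tested, and the genotype stays open.

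Pollen-expressed genes among the 15 lowest may reflect pollen RNA in the wild-type library. A list of 18 other pollen markers was written after those 15 were seen and before any value of its members was, and 13 were in the table, with 474 reads in wild type and 110 in dcl1-5. The median log2 ratio of the 8 with at least 5 reads was -1.92, and 6 were lower in dcl1-5, the most abundant being AT5G45880 (149 and 21 reads) and AGP6 (117 and 21). The markers did not share 1 ratio, however, and VGDH1 and AT1G29140 had more reads in dcl1-5: VGDH1 had 24 and 32 reads, a ratio of 1.66 [0.946 to 2.94], against 0.175 [0.105 to 0.278] for AT5G45880, so pollen RNA would not account for each marker. How many of these genes the embryo expresses itself was not analysed here, hand dissection would be the step that removes pollen, and a difference between the genotypes stays open.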
